A study of Mus musculus with 10 samples.

How the data were processed

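RNA polymerase II was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse primary Th1 cells of the strain Balb/c DO11.10, with the antibody 8WG16 (ab817), per the labels. Per the labels' protocols, peripheral CD4+ T cells were primed under Th1 conditions, expanded with an interleukin 2 analogue, rested for a day without it and restimulated with plate-bound anti-CD3 at 5 µg/ml and soluble anti-CD28 at 2.5 µg/ml. Chromatin was fixed in 1% formaldehyde for 10 min, and fragments of 360 to 600 bp were selected for the libraries. The 6 polymerase libraries form 3 groups of 2: cells not restimulated (NR), cells restimulated for 30 min and cells restimulated for 2 h. The series also lists 3 libraries for histone H3 trimethylated at lysine 36 and 1 input library, which were not analysed here. The labels call the libraries replicates but do not say whether they came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

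The deposited peaks were called separately in each library rather than on pooled replicates, since each library has its own lists, per the labels. BWA 0.7.13, Picard 1.119, MACS2 2.1.0 and the genome build mm10 are named in the submitters' processing notes, which give no role or order. Each library has a deposited list of all peak summits and a deposited table of the peaks within 1000 bp of a transcription start site. Every peak in that table is in the promoter class and is assigned by the authors to a single gene. The tool behind the assignment is not given in the sources used here. For each peak the deposited tables give the signal as a pileup (coverage at the summit), a fold enrichment, which is a ratio to local background, and the −log10 of a p-value and of a q-value, per the file headers and the values. The smallest −log10 q in any deposited list is 1.31. These values belong to a peak within its own list, and here they only described, ranked or filtered peaks inside a list. None was compared between libraries.

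The lists hold no read counts. The length of DNA called as a promoter peak and assigned to a gene was therefore the value compared between libraries, beside the presence or absence of a peak. Called length was taken as log2(bp + 100), so a fold change understates the change of a gene with little called DNA. Each library was centred on its median over the 7410 genes with an assigned peak in all 6 libraries. Genes with a peak in at least 2 libraries were kept, which left 9908 of 10419. The fit was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) over all 6 libraries, with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 changes, standard errors (SE) and adjusted p-values in the text come from this fit unless another is named. A group of 2 libraries against 2 gives 3 splits, so no permutation of those libraries can give a p under 0.333. A gene with no peak in both libraries of a group is said to be listed with no peak, and no fold is given for it. Its values in that group are the pseudocount, and differ only by the centring shifts. That group thus adds no measured spread to its SE and p-value, which may be too small.

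Presence was counted as peaks in both libraries of one group and in neither of the other, for genes and for 10991 regions made by merging promoter peaks that overlap by at least 1 bp. Each count was set beside the counts of the other 2 ways to split the 4 libraries. One puts libraries with the same replicate number together, and the crossed split puts replicate 1 of one group with replicate 2 of the other. Of the 21 gene lists fixed, 18 had enough genes for limma's camera test with a preset correlation of 0.01 between genes, two-sided, adjusted over the lists. An estimated correlation was the alternative. It is not a test of correlation alone, since adjusted p also rose where the estimate lay under 0.01. For ribosomal protein genes at 30 min, with an estimate of 0.00885, it rose from 1.19e-05 to 0.0787. Lists among genes that gained a peak were tested with a one-sided Fisher's exact test against genes with no peak in either NR library and a peak in at least 1 stimulated library. Genes with no peak in any library are thus left out, and an alternative keeps them. The counts called "adjusted over the list alone" come from the same p-values corrected within a list. Overlap of the peak lists was the Jaccard index in bp, with an exact permutation test over the 15 ways to pair 6 libraries.

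The comparisons, gene lists, tests, alternative settings and naming rule were set before the data were examined. Per comparison with NR the rule names the 10 genes with the largest rise and the 5 with the largest fall among those past the threshold whose groups do not overlap (5 and 5 for 2 h against 30 min). Open places go to genes of the fixed lists with the largest change whose groups do not overlap, said to have missed the test. Overlap of groups was judged on bp before centring. Fos, Egr1, Egr2, Nr4a1, Myc, Ifng, Il2, Tnf, Nfkbia, Tnfaip3, Irf4, Tbx21, Gata3, Klf2, Cd4, Cd3e and Actb are always named, and each list described has 2 to 4 members with the largest change. MicroRNA and small nucleolar RNA genes and symbols that are only model names are counted but not named. Where a count of 5 or fewer has a member outside the rule, that member is named as chosen after its values were seen.

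Alternatives set beforehand changed the pseudocount (1000 or 10 bp), the centring (none, or quantile normalisation), the filter, the peak threshold (−log10 q of at least 5), the list length (the 9074 strongest promoter peaks of each library), the value (number of summits), the libraries in the fit, the term for replicate number and the overlap of regions (50% of the shorter peak). The rest were added after seeing the data. For lists among gained genes, the background became all protein-coding genes with no NR peak, under either assignment. Assignment by position drops the authors' assignment. It counts, for each protein-coding gene, the called bp of promoter peaks inside the gene's span with 1000 bp on each side. Gene spans came from a RefSeq table of the assembly GRCm38.p6, the same build as mm10. Of the 10419 symbols in the peak tables, 9979 matched it, and the gene's span in the peak table overlapped that of RefSeq for 99.8% of them. A value by position cannot exceed the span with its flanks, and it has no value for the histone genes, whose symbols differ in that table. Coordinates are 1-based, on mm10.

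Depth is given in no file. It was inferred from each library's background pileup (pileup over fold enrichment), its smallest peak width as the fragment length and MACS2's default mouse genome size. Pileups in replicate 2 of each group lie on steps under 1 (0.577, 0.708 and 0.65, within 0.0051), as MACS2 gives when it scales a library down. The read numbers in the text are these estimates, before scaling.

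The limma step was tested on simulated data for 30 min against NR, with 200 of 9908 genes changed. With residuals drawn from the real fit it called 22% of genes changed by 1 on the log2 scale, 68% of those changed by 2, 80% by 3 and 96% by 5, with 8 false calls. With residuals drawn from a normal distribution it called 12%, 64%, 68% and 86%, with 7 false calls. The changes were put into the 30 min and the 2 h libraries alike. Noise was drawn independently around the NR mean of each gene, with no floor for genes without a peak. The real deviations of same-numbered libraries correlated at 0.44 for 30 min against NR, so these rates may not hold for the real libraries. Other tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.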

Results

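RNA polymerase II was mapped by ChIP-seq in 6 libraries of mouse Th1 cells, the T helper cells that make interferon gamma. NR cells, cells restimulated through the T cell receptor and CD28 for 30 min and cells restimulated for 2 h gave 2 libraries each. The lists held 19888 and 17627 peaks in the NR libraries (replicates 1 and 2), 15330 and 23299 at 30 min, and 20086 and 21743 at 2 h. Of these, 9360 and 10383, 9074 and 10680, and 10549 and 10658 lay at promoters. The called promoter DNA came to 10.3 ± 2.20 Mb in NR cells, 13.6 ± 6.52 Mb at 30 min and 16.1 ± 2.63 Mb at 2 h (SD, n = 2). Peaks wider than 5 kb numbered 87.5 ± 26.2, 312.5 ± 245 and 338.5 ± 81.3. Depth differed widely between libraries. Replicates 1 had an inferred 4.58 M (NR), 12.9 M (30 min) and 22.1 M reads (2 h), with M for the prefix mega, and replicates 2 had 39.4 M, 32.1 M and 35.0 M. NR replicate 1 was the shallowest library and NR replicate 2 the deepest.

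The Jaccard index of promoter peaks was 0.638 ± 0.131 within groups (n = 3 pairs) and 0.606 ± 0.0964 between groups (n = 12 pairs). The exact permutation test (p = 0.4, one-sided) cannot give a p under 0.0667 with 15 pairings, so whether libraries of a group resemble each other more is left open. Of 10991 merged promoter regions, 7728 had a peak in all 6 libraries. Of 10419 genes with an assigned peak in any library, 7410 had one in all 6. Centring on these genes removed a shift of 0.16 on the log2 scale at 30 min against NR, 0.48 at 2 h against NR and 0.32 at 2 h against 30 min. Changes below are relative to it.

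The first comparison asks where polymerase was called after 30 min of restimulation. Longer called peaks were found for 4 of 32 immediate early genes and 3 of 20 effector cytokine and chemokine genes, and the effector list did not pass with an estimated correlation (adjusted p = 0.127). Egr2 (chromosome 10, 67534469 to 67542188) and Egr3 (chromosome 14, 70077317 to 70082613), zinc finger transcription factors induced by T cell receptor signals, were listed with no peak in either NR library. At 30 min their peaks covered 10089 ± 3162 bp (adjusted p = 0.000627) and 15972 ± 1698 bp (adjusted p = 0.00102; SD, n = 2). Nr4a3, an orphan nuclear receptor gene on chromosome 4 (48045078 to 48086447), rose from 553.5 ± 105 to 20897 ± 8805 bp, a log2 change of 4.79 ± 0.18 (SE, adjusted p = 0.00133). Cd40lg, the ligand of CD40 (chromosome X, 57212143 to 57224042), rose by 3.92 ± 0.25 (adjusted p = 0.00905).

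In all, 23 genes had longer called peaks and 1 had shorter ones among 9908 tested with limma, and 793 had an unadjusted p under 0.05. A pseudocount of 1000 bp gave 33 and 7, assignment by position 14 and 0, only the 4 libraries 13 and 3, and the number of summits 67 and 40. Of the 23, 7 are microRNA or small nucleolar RNA genes or bear only model names, and are not named. These have no value by position, so assignment to them of DNA from an overlapping gene was not checked and stays possible. Of the genes with an assigned peak in both NR libraries and neither 30 min library, 28 had a value by position. Of these, 71.4% kept a called peak in all 4 libraries there. The chemokine genes Ccl4 and Ccl3, neighbours on chromosome 11, were listed with no peak in NR cells and had 5068.5 ± 293 bp (adjusted p = 0.00356) and 2526 ± 1758 bp (adjusted p = 0.0107) at 30 min. Egr1 (chromosome 18, 34861207 to 34864956) rose from 752.5 ± 316 to 10091.5 ± 4211 bp, a log2 change of 3.41 ± 0.19 (adjusted p = 0.00735). Nfkbia, which encodes the NF-kB inhibitor IkB alpha, rose by 2.34 ± 0.23 from 1338.5 ± 312 bp (adjusted p = 0.0422). Pdcd1, the gene of the inhibitory receptor PD-1, rose by 1.87 ± 0.19 (adjusted p = 0.0452). The pseudogene Slc2a4rg-ps was listed with no peak in NR cells and had 1049 and 3026 bp at 30 min (adjusted p = 0.0422). The tyrosine kinase gene Fes rose by 3.42 ± 0.34 (adjusted p = 0.0452) and Hcst, which encodes the adaptor DAP10, by 3.24 ± 0.29 (adjusted p = 0.0306). Counted by position neither passed the test (adjusted p = 0.578 for Fes, and a log2 change of 0.84 for Hcst). The 1 gene with shorter peaks was Shisa5, which fell by 3.46 on the log2 scale (SE 0.14, adjusted p = 0.00160), and by position its value was 0.05. Rps27, a ribosomal protein gene chosen after its values were seen, rose by 2.34 ± 0.19 (adjusted p = 0.0216). Of the 23 longer genes 15 had a value by position, all in the same direction, and 8 passed there. Egr1 (2.68, adjusted p = 0.0661), Nfkbia (1.69, adjusted p = 0.110), Pdcd1 (1.72, adjusted p = 0.0834) and Rps27 (1.25, adjusted p = 0.223) did not. A value by position is capped at the gene's span with its flanks. For Egr1 that cap lies under the 10091.5 bp assigned at 30 min, so the cap can lower the change of such short genes. By the number of summits the direction turned for Cd40lg (-0.37), Hcst (-1.53) and Nfkbia (-0.61).

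**Figure D1:**
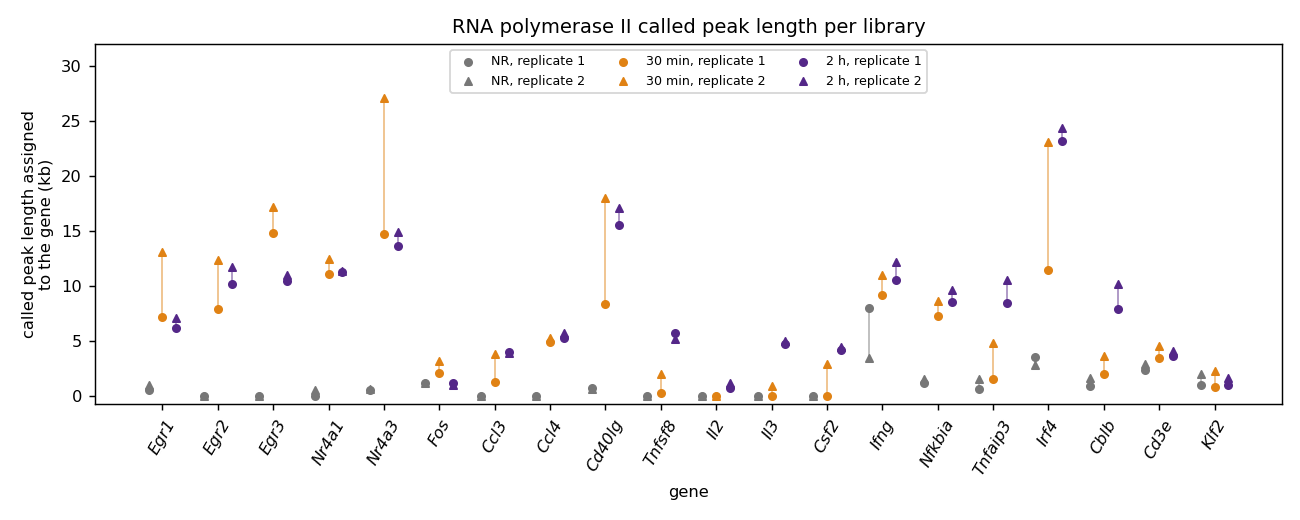
Called peak length assigned to each of 20 genes (kb, vertical axis) in each library; circles are replicate 1, triangles replicate 2, and colour gives the group. Egr2 and Egr3 lie at 0 in both NR libraries and between 7853 and 17173 bp at 30 min, and Il2 has a peak in the 2 h libraries.

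Other genes set for naming did not pass at 30 min. Nr4a1 had 0 and 483 bp in the NR libraries and 11034 and 12478 bp at 30 min (adjusted p = 0.0766). Fos had 1138 ± 31.1 bp in NR cells and 2589.5 ± 790 bp at 30 min (adjusted p = 0.275). Myc had 4810.5 ± 224 and 9315.5 ± 489 bp (adjusted p = 0.635). Irf4, a transcription factor of activated lymphocytes, had 3142.5 ± 524 and 17278 ± 8253 bp (adjusted p = 0.150). Tbx21, which encodes the Th1 factor T-bet, had 2234 ± 198 and 7875 ± 1187 bp (adjusted p = 0.340). Ifng had peaks in both NR libraries (8006 and 3459 bp) and 9191 and 10957 bp at 30 min (adjusted p = 0.751). Il2 was listed with no peak in either group. Tnfaip3 gave an adjusted p of 0.532, Cd3e 0.647, Actb 0.728, Gata3 0.789, Klf2 0.913 and Cd4 0.947. Promoter peaks at Tnf were assigned by the authors to neighbouring genes. By position Tnf had 4641 bp in each of the 6 libraries, which is the most that measure allows, so it could show no change. Nfkbid, Rps12, Rpl12 and Rpl27a were the list genes with the largest negative values, with assigned peaks in both NR libraries and none at 30 min, and missed the test (adjusted p = 0.0915, 0.119, 0.273 and 0.275). By position these genes had log2 changes of 1.76, 0.61, 0.96 and 1.15.

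The 30 min counts rested on single libraries. Without NR replicate 1, 4 genes were longer and 0 shorter. Without NR replicate 2 there were 24 and 1, without 30 min replicate 1 53 and 15, and without 30 min replicate 2 52 and 175. Without 2 h replicate 1 or 2 h replicate 2 there were 5 and 2, and 9 and 2. Egr2 and Egr3 passed with each of the 6 libraries left out, and without NR replicate 1 they were the only 2 kept of the 12 called genes that are always named or had the largest changes. Egr2 and Egr3 have no peak in either NR library, so leaving out an NR library keeps their NR values at the pseudocount, apart from centring. For them the removal of an NR library is therefore a weak test. In bp before centring, groups did not overlap for 1254 genes (12.7%, where exchangeable libraries give 33.3%). The shifts that centring removes put the 30 min libraries (-0.446 and 0.341) on either side of the NR libraries (-0.377 and -0.048). This library-wide difference lowers the share.

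Among the lists fixed for these cells, 13 had longer called peaks and 1 shorter ones at 30 min by camera with a preset correlation. Of 32 immediate early genes, 4 rose (Egr1, Egr2, Egr3 and Nr4a3), 0 fell and 28 did not pass, and adjusted over the list alone 16 rose. Their median log2 change was 0.88 (adjusted p = 8.08e-19; adjusted p = 0.0330 with an estimated correlation). This was the only list to pass with an estimated correlation. Of 20 effector cytokine and chemokine genes, 3 rose (Ccl3, Ccl4 and Cd40lg) and 17 did not pass, and 5 rose adjusted over the list alone. Their median was 1.17 (adjusted p = 4.55e-08; adjusted p = 0.127 with an estimated correlation). Tnfsf8, which encodes CD30 ligand, had 250 and 1932 bp at 30 min against no peak in NR cells and missed the test (adjusted p = 0.223). Of 18 activation receptors, 1 rose (Pdcd1) and 17 did not pass, and 6 rose adjusted over the list alone, with a median of 0.95 (adjusted p = 2.52e-07; adjusted p = 0.0787 with an estimated correlation). Slamf1 (2.30, adjusted p = 0.0912) and Cd69 (2.38, adjusted p = 0.142) were among the largest of those that did not pass. Of 22 NF-kB genes, 1 rose (Nfkbia) and 21 did not pass, and adjusted over the list alone 5 rose and 1 fell, with a median of 0.61 (adjusted p = 1.03e-09; adjusted p = 0.0518 with an estimated correlation). Bcl2a1b, a Bcl-2 family survival gene of that list, had a log2 change of 1.42 (adjusted p = 0.0534).

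In 8 more lists called longer at 30 min, no member passed over all genes. These were activation transcription factors (20 genes, median 0.53, adjusted p = 0.000753; adjusted p = 0.179 with an estimated correlation), the Th1 programme (16 genes, 0.48, 0.000320; adjusted p = 0.137 with an estimated correlation) and pan T cell genes (20 genes, 0.51, 0.000258; adjusted p = 0.179 with an estimated correlation). Feedback and mRNA decay regulators (22 genes, 0.30, 0.0231; adjusted p = 0.160 with an estimated correlation), glycolysis (17 genes, 0.14, 0.00174; adjusted p = 0.298 with an estimated correlation) and ribosome biogenesis (23 genes, 0.29, 0.00876; adjusted p = 0.200 with an estimated correlation) were others. The last were interferon response (24 genes, 0.29, 0.000258; adjusted p = 0.160 with an estimated correlation) and housekeeping genes (17 genes, 0.34, 0.000320; adjusted p = 0.137 with an estimated correlation). Adjusted over the list alone, 6 activation transcription factors, 3 pan T cell, 1 glycolysis, 3 interferon response and 2 housekeeping genes rose, and 0 of the others. Examples are Zap70 (1.43, adjusted p = 0.109), the glycolytic enzyme gene Pkm (1.62, adjusted p = 0.0720), the guanylate-binding protein gene Gbp3 (1.40, adjusted p = 0.0912) and the translation factor gene Eef1a1 (1.85, adjusted p = 0.133). None of these passed. Of 74 ribosomal protein genes 1 rose and 73 did not pass, and adjusted over the list alone 1 rose and 1 fell, with a median of 0.34 and a mean of 0.03 (adjusted p = 1.19e-05; adjusted p = 0.0787 with an estimated correlation). The 37 histone genes were shorter (median -0.20, and -0.04 with no centring; adjusted p = 0.000147; adjusted p = 0.439 with an estimated correlation), and none passed alone. Quiescence genes (19 genes, 1 rising adjusted over the list alone, median -0.19, adjusted p = 0.368), other T helper lineages (10 genes, 0.29, 0.163) and cell cycle genes (25 genes, 0.03, 0.715) did not pass.

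Several 30 min list calls ended when 1 library was left out. Without NR replicate 2, adjusted p was 0.0785 for activation transcription factors, ribosome biogenesis and housekeeping genes, 0.189 for the Th1 programme, 0.147 for feedback regulators and glycolysis and 0.179 for interferon response. Without 30 min replicate 1 it was 0.561 for feedback regulators and 0.254 for ribosome biogenesis. Without 30 min replicate 2 it was 0.133 for pan T cell genes, 0.104 for glycolysis and 0.0507 for ribosome biogenesis, and 0.925 for histone genes, whose direction turned. With quantile normalisation the adjusted p was 0.248 for activation transcription factors, 0.104 for the Th1 programme, 0.123 for pan T cell genes, 0.560 for feedback regulators and 0.0535 for housekeeping genes, and quiescence genes passed as shorter (0.00176). With the stricter peak threshold it was 0.0521 for feedback regulators. By the number of summits only activation receptors passed.

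**Figure D2:**
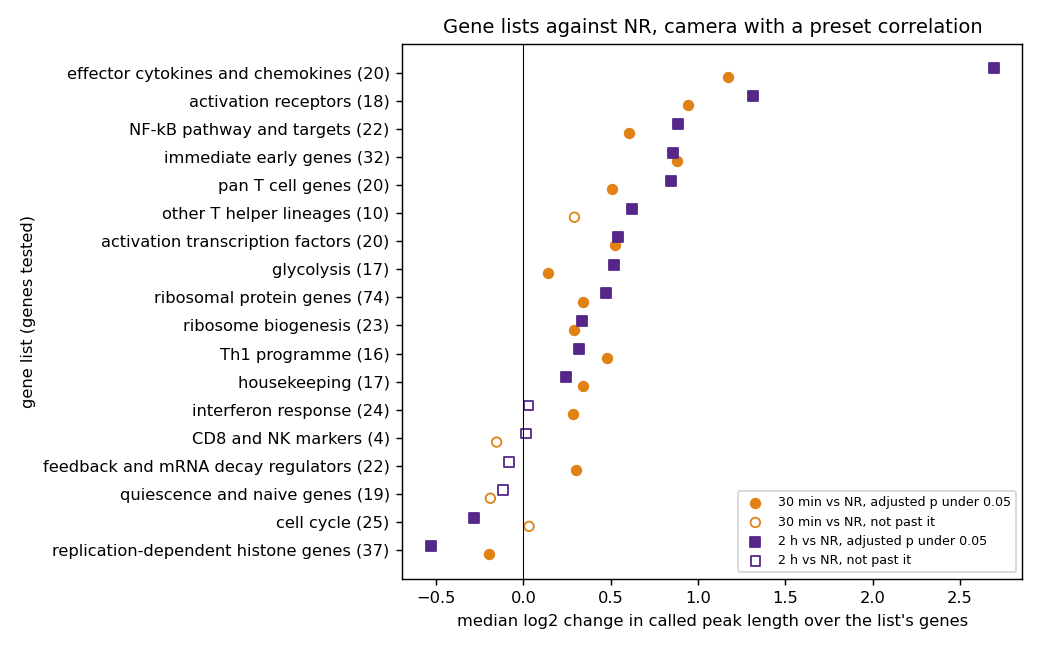
Median log2 change in called peak length of each fixed gene list (horizontal axis) against NR at 30 min and at 2 h; filled points passed camera at an adjusted p under 0.05 with the preset correlation. Cytokine and chemokine genes have medians of 1.17 and 2.70, and histone genes, at -0.20 and -0.53, lie near 0 with no centring (-0.04 and -0.05).

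Promoter peaks appeared at some immediate early genes by 30 min. A peak in both 30 min libraries and neither NR library was found for 39 genes, and 38 showed the reverse. Of the 5 immediate early genes with no NR peak and a peak in at least 1 stimulated library, 3 gained one, Egr2, Egr3 and Fosb (one-sided Fisher's exact test against 840 such genes, adjusted p = 0.00783). Of 11 cytokine and chemokine genes, Ccl3, Ccl4 and Tnfsf8 gained a peak (adjusted p = 0.0531). Against all 13204 protein-coding genes with no assigned NR peak, these were 3 of 6 and 3 of 16 genes (Fisher's exact test, adjusted p = 2.16e-06 and 2.99e-05). That background also holds genes with no assigned peak in any library, and genes such as Tnf whose NR peaks were assigned to a neighbour. By position it held 11387 genes, and these were 3 of 5 and 3 of 13 (adjusted p = 1.31e-06 and 1.84e-05). By position, 25 genes gained and 1 lost a peak, and the 1 lost was Ms4a4c, chosen after its values were seen. Over merged regions, 44 gained and 2 lost a peak.

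These 30 min counts moved with single libraries and were small beside differences between replicates. The same 4 libraries split by replicate number differed at 920 regions and 895 genes, and the crossed split at 15 regions and 21 genes. Without NR replicate 1, NR replicate 2, 30 min replicate 1 and 30 min replicate 2 in turn, the regions gained and lost were 48 and 85, 370 and 32, 762 and 2, and 51 and 664. The genes gained and lost were 48 and 109, 354 and 121, 474 and 118, and 135 and 663. With lists of equal length 103 regions gained and 56 lost a peak, as did 97 and 66 genes, and the adjusted p of immediate early genes was 0.101.

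**Figure D3:**
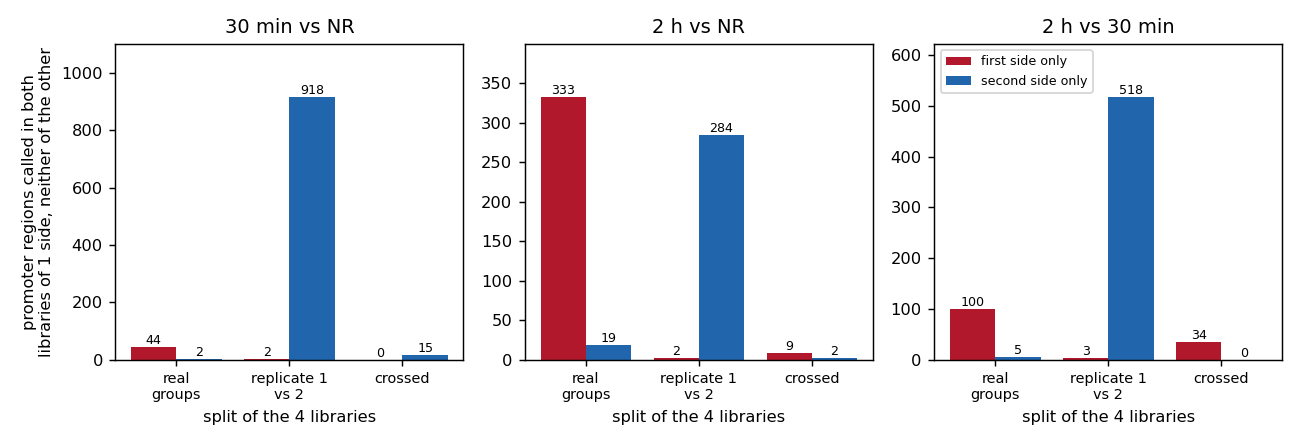
Number of promoter regions with a peak in both libraries of one side and neither of the other (vertical axis), for the real groups, for replicate 1 against replicate 2 and for the crossed split, in each comparison. At 30 min against NR the replicate split gives 920 regions and the groups 46, and at 2 h against NR 286 and 352.

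The next comparison asks the same after 2 h of restimulation. Of 25 cytokine and chemokine genes listed, 8 and 9 already had an assigned promoter peak in NR replicates 1 and 2. These counts leave out genes such as Tnf, whose peaks were assigned to neighbouring genes. In any library 20 had an assigned peak, and 23 had a peak by position. By assignment, 12 and 18 had a peak at 30 min, and 20 and 19 at 2 h. Of 11 such genes with no NR peak and a peak in at least 1 stimulated library, 10 had a peak in both 2 h libraries: Ccl1, Ccl3, Ccl4, Ccl5, Csf2, Il2, Il3, Tnfsf8, Tnfsf11 and Tnfsf14 (one-sided Fisher's exact test, adjusted p = 0.000691; 0.0152 with lists of equal length, 0.00373 by position). They were 10 of 16 when listed genes with no assigned peak in any library, Tnf among them, are kept (adjusted p = 6.99e-14 against all protein-coding genes with no assigned NR peak). By position, with the same kind of background, they were 10 of 13 (adjusted p = 1.4e-14). Ccl4 had 5443.5 ± 337 bp (adjusted p = 0.00441), Ccl3 3897.5 ± 77.1 bp (adjusted p = 0.00725) and Tnfsf8 5466.5 ± 381 bp (adjusted p = 0.0470), against no peak in NR cells. Cblb, which encodes a ubiquitin ligase that restrains T cell receptor signalling (chromosome 16, 52031230 to 52208047), rose from 1238.5 ± 531 to 9038.5 ± 1592 bp, a log2 change of 2.34 ± 0.20 (adjusted p = 0.0208).

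At 2 h 37 genes were longer and 6 shorter than in NR cells by limma, 8 and 2 of them not named for the same reason, and 1249 had an unadjusted p under 0.05. With no centring there were 35 and 1, with quantile normalisation 86 and 24, with a pseudocount of 1000 bp 93 and 19, with lists of equal length 71 and 15, with only the 4 libraries 148 and 25, with the stricter peak threshold 27 and 2, and by the number of summits 137 and 41. Egr2 and Egr3 had 10937 ± 1088 bp (adjusted p = 0.000724) and 10709 ± 359 bp (adjusted p = 0.00155) against no NR peak. Cd40lg rose from 631 ± 70.7 to 16295 ± 1114 bp (log2 change 4.01 ± 0.25, adjusted p = 0.00725) and Nr4a3 to 14258 ± 911 bp (3.99 ± 0.18, adjusted p = 0.00283). Lilrb4a, an inhibitory receptor gene, rose by 3.02 ± 0.20 (adjusted p = 0.00848), Egr1 by 2.55 ± 0.19 (adjusted p = 0.0132) and Nfkbia by 2.21 ± 0.23 (adjusted p = 0.0350). Fes rose by 2.97 ± 0.34 (adjusted p = 0.049973), and by position its value was 0.92. By the number of summits the direction turned for Cd40lg (-0.98), Lilrb4a (-0.74), Nfkbia (-0.61) and Fes (-0.37). Dnaaf2, listed with no NR peak, had 1930.5 ± 58.7 bp (adjusted p = 0.0312), and by position its log2 change was 0.49. Cd274, the gene of PD-L1, and Bcl2a1b, both chosen after their values were seen, rose by 2.13 ± 0.20 (adjusted p = 0.0282) and 1.72 ± 0.15 (adjusted p = 0.0219).

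The genes with shorter peaks at 2 h that had a value by position kept called DNA there. Shisa5 fell by 3.96 on the log2 scale (SE 0.14, adjusted p = 0.00129), and its value by position was -0.23. Rps3a1 and Obsl1 had 1096.5 ± 460 and 966 ± 352 bp in NR cells and no assigned peak at 2 h (adjusted p = 0.0173 and 0.0350), and by position their log2 changes were 1.43 and 0.74. The small nucleolar RNA host gene Gas5 had 3123.5 ± 250 bp in NR cells and no assigned peak at 2 h (adjusted p = 0.049973), with no value by position. Of the 37 longer genes 28 had a value by position, all in the same direction, and 16 passed there. Egr1 (2.33, adjusted p = 0.0800), Nfkbia (1.41, adjusted p = 0.130) and Cd274 (1.80, adjusted p = 0.0997) did not. The cap on values by position may lower the change of short genes such as Egr1. Of the 6 shorter genes 3 had a value by position, of which 1 kept its direction and 0 passed. By position limma called 24 longer and 0 shorter genes. Zc3h12d, which encodes an RNase, had 3378 and 3616 bp in NR cells and no assigned peak at 2 h, and missed the test (adjusted p = 0.145; by position 0.25).

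Other genes set for naming did not pass at 2 h. Il2 (chromosome 3, 37120713 to 37125954) had 683 and 1135 bp at 2 h and no peak in NR cells (adjusted p = 0.337). Il3 and Csf2, neighbouring cytokine genes on chromosome 11, had 4839 ± 221 and 4285.5 ± 213 bp at 2 h and no peak in NR cells (adjusted p = 0.0946 and 0.246). Nr4a1 had 11213 and 11338 bp (adjusted p = 0.0738). Tnfaip3, which encodes the NF-kB regulator A20, had 1060 ± 668 bp in NR cells and 9474 ± 1455 bp at 2 h (adjusted p = 0.0810). Irf4 had 3142.5 ± 524 and 23747 ± 867 bp (adjusted p = 0.0881). Ifng had 5732.5 ± 3215 and 11360 ± 1153 bp (adjusted p = 0.660). Fos had 1138 ± 31.1 and 1044 ± 93.3 bp (adjusted p = 0.342). Adjusted p was 0.446 for Tbx21, 0.465 for Cd4, 0.502 for Myc, 0.522 for Klf2, 0.715 for Actb, 0.834 for Gata3 and 0.865 for Cd3e.

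**Figure D4:**
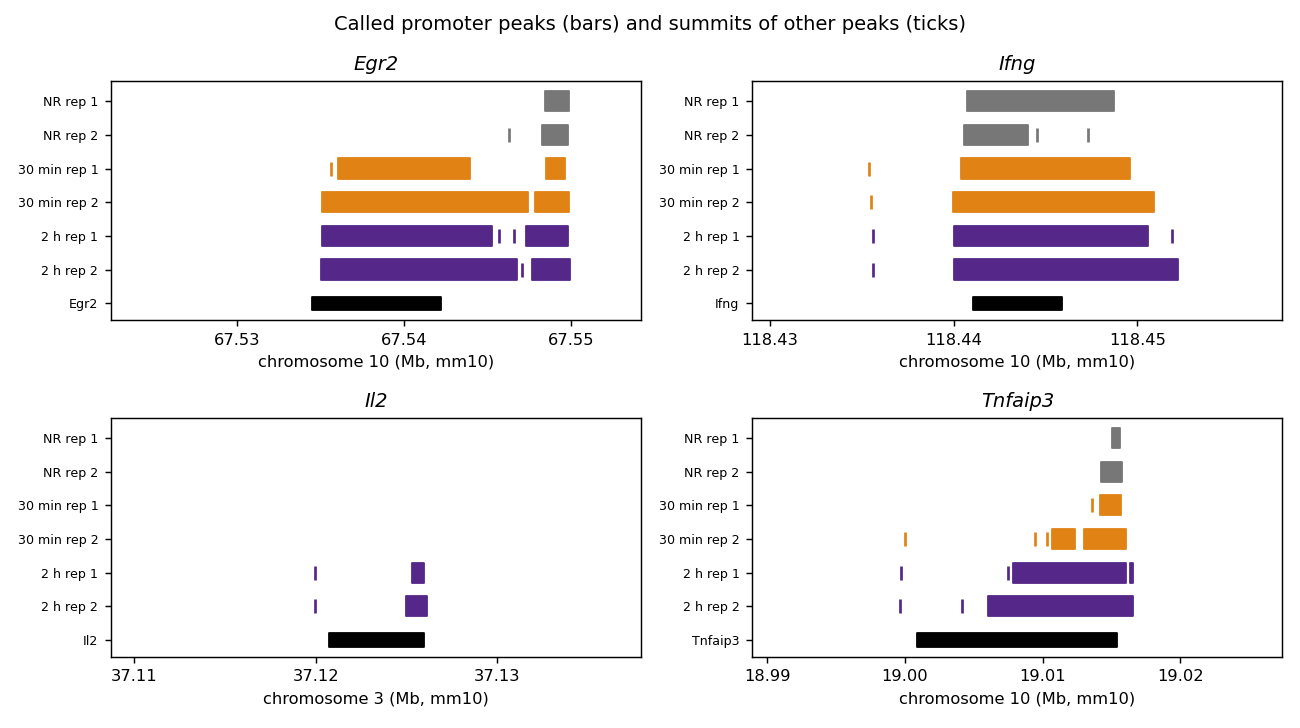
Called promoter peaks (bars) and summits of other peaks (ticks) in each library around Egr2, Ifng, Il2 and Tnfaip3, with the gene span in black; the horizontal axis is the position on the chromosome (Mb, mm10). Il2 shows a promoter peak of 683 and 1135 bp in the 2 h libraries, and Ifng shows promoter peaks in all 6 libraries.

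The number of genes called at 2 h also rested on single libraries. Without NR replicate 1, NR replicate 2, 30 min replicate 1, 30 min replicate 2, 2 h replicate 1 and 2 h replicate 2 in turn, limma called 4 longer and 0 shorter, 34 and 1, 138 and 20, 145 and 41, 3 and 2, and 4 and 2 genes. Egr2 and Egr3 passed in each of these fits, and were the 2 kept without NR replicate 1 of the 15 such genes tested there. For Egr2 and Egr3, whose NR values lie at the pseudocount, the removal of an NR library is again a weak test. In bp before centring, groups did not overlap for 5388 genes (54.4%, where exchangeable libraries give 33.3%). The shifts that centring removes were higher in both 2 h libraries (0.147 and 0.382) than in both NR libraries (-0.377 and -0.048). The share therefore includes a library-wide shift and does not measure changes of single genes.

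At 2 h, 12 lists had longer and 2 shorter called peaks with a preset correlation, and none passed with an estimated one. Of 20 cytokine and chemokine genes, 4 rose (Ccl3, Ccl4, Cd40lg and Tnfsf8), 0 fell and 16 did not pass, and adjusted over the list alone 11 rose. The median log2 change was 2.70 (adjusted p = 1.80e-10; adjusted p = 0.0863 with an estimated correlation). Of 32 immediate early genes, 4 rose and 28 did not pass, and 16 rose adjusted over the list alone, with a median of 0.86 (adjusted p = 6.07e-10; adjusted p = 0.0600 with an estimated correlation). Of 18 activation receptors, 1 rose (Cd274) and 17 did not pass, and 10 rose adjusted over the list alone, with a median of 1.32 (adjusted p = 2.70e-09; adjusted p = 0.0621 with an estimated correlation). Havcr2, which encodes TIM-3, had 2103 and 1828 bp at 2 h and no NR peak (adjusted p = 0.149). Of 22 NF-kB genes, 2 rose (Nfkbia and Bcl2a1b) and 20 did not pass, and adjusted over the list alone 11 rose and 1 fell, with a median of 0.89 (adjusted p = 3.33e-09; adjusted p = 0.0600 with an estimated correlation). Birc3 of that list had a log2 change of 1.84 (adjusted p = 0.0916).

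Metabolic and protein synthesis lists were longer at 2 h as well. Glycolysis genes had a median of 0.52 (17 genes, 2 rose adjusted over the list alone, adjusted p = 2.06e-05; adjusted p = 0.208 with an estimated correlation), with Gapdh at 1.40 (adjusted p = 0.320). Ribosome biogenesis genes had 0.34 (23 genes, adjusted p = 0.000237; adjusted p = 0.160 with an estimated correlation). Of 74 ribosomal protein genes 1 rose (Rps27, 2.22, adjusted p = 0.0207, and by position 0.97, adjusted p = 0.258), 1 fell (Rps3a1) and 72 did not pass, and adjusted over the list alone 9 rose and 3 fell, with a median of 0.47 and a mean of -0.13, which differ in sign (adjusted p = 4.41e-05; adjusted p = 0.0863 with an estimated correlation). Pan T cell genes had 0.85 (20 genes, adjusted p = 0.000439; adjusted p = 0.208 with an estimated correlation) and activation transcription factors 0.54 (20 genes, 4 rose adjusted over the list alone, adjusted p = 0.000258; adjusted p = 0.187 with an estimated correlation). The Th1 programme (16 genes, 0.32, adjusted p = 0.0391; adjusted p = 0.228 with an estimated correlation), other T helper lineages (10 genes, 0.62, adjusted p = 0.0350; adjusted p = 0.296 with an estimated correlation) and housekeeping genes (17 genes, 0.24, adjusted p = 0.0293; adjusted p = 0.223 with an estimated correlation) also passed. Histone genes were shorter (37 genes, median -0.53, and -0.05 with no centring; adjusted p = 8.14e-13; adjusted p = 0.208 with an estimated correlation). Cell cycle genes were shorter too (25 genes, median -0.28, and 0.19 with no centring, which turns the direction; adjusted p = 0.00269; adjusted p = 0.118 with an estimated correlation), although Ccnd2, the gene of cyclin D2, had 1.21 (adjusted p = 0.271). Feedback regulators (22 genes, 1 rose, median -0.08, mean 0.21, adjusted p = 0.196), quiescence genes (-0.12, 0.242) and interferon response genes (0.03, 0.867) did not pass. Apart from Cblb and the ribosomal protein genes, no member of the lists in this paragraph passed over all genes. Adjusted over the list alone, 6 feedback regulators rose and 1 fell, and 1 housekeeping gene rose.

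Some 2 h list calls ended when 1 library was left out. Without NR replicate 2, adjusted p was 0.813 for the Th1 programme, 0.251 for other T helper lineages and 0.400 for housekeeping genes. It was 0.0507 for the Th1 programme without 30 min replicate 2 and 0.0739 for housekeeping genes without 2 h replicate 1. Without 2 h replicate 2 it was 0.126 for the Th1 programme and 0.296 for other T helper lineages. Without NR replicate 1 feedback regulators passed (adjusted p = 0.0253). By position the Th1 programme, other T helper lineages and housekeeping genes did not pass (adjusted p = 0.238 for each). With quantile normalisation it was 0.457, 0.131 and 0.209 for these and 0.0587 for activation transcription factors, and quiescence genes passed as shorter (0.0400). Other T helper lineages did not pass with no centring (0.134), the stricter peak threshold (0.0814) or lists of equal length (0.145), nor housekeeping genes with the stricter threshold (0.0814), the Th1 programme with a pseudocount of 10 bp (0.0590) or only the 4 libraries (0.0526), or cell cycle genes with no centring (0.154). With a pseudocount of 1000 bp feedback regulators passed (0.0160). By the number of summits only activation receptors passed.

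Gains of promoter peaks outnumbered losses at 2 h. Over regions 333 gained and 19 lost a peak, and over genes 268 gained and 69 lost one (210 and 10 by position). With lists of equal length gains and losses were 244 and 123 regions, and 238 and 152 genes. The replicate split of these libraries differed at 286 regions and 290 genes, and the crossed split at 11 and 26. Without NR replicate 1, NR replicate 2, 2 h replicate 1 and 2 h replicate 2 in turn, the regions gained and lost were 344 and 170, 1216 and 55, 752 and 22, and 487 and 112. The genes were 286 and 188, 1103 and 175, 528 and 120, and 374 and 164. Of the 5 immediate early genes with no NR peak and a peak in at least 1 stimulated library, 4 gained one (adjusted p = 0.172). Against all protein-coding genes with no assigned NR peak these were 4 of 6 (adjusted p = 6.35e-06), and 4 of 5 by position (adjusted p = 3.88e-06).

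The last comparison asks what differed between 2 h and 30 min. No single gene passed limma in either direction, and 513 had an unadjusted p under 0.05. A pseudocount of 1000 bp gave 5 longer and 3 shorter, and the number of summits 91 and 31. Il3 had 0 and 856 bp at 30 min and 4683 and 4995 bp at 2 h (adjusted p = 0.564), Ccl1 and Il2 no peak at 30 min and 1061 and 1143 bp, and 683 and 1135 bp, at 2 h (adjusted p = 0.655 and 0.804). Cd200 and Tap1 were the next list genes by size (3.12 and 3.22, adjusted p = 0.866 for both), and by position Tap1 had -0.23. Fos had 2031 and 3148 bp at 30 min and 1110 and 978 bp at 2 h (log2 change -1.52 ± 0.20, adjusted p = 0.240). Fosb (-1.36, adjusted p = 0.725), Gbp3 (-1.07, adjusted p = 0.426) and, with no assigned peak at 2 h, Rps3a1 and Zc3h12d (adjusted p = 0.107 and 0.614) made up the other negative values. Adjusted p was 0.564 for Egr1, 0.673 for Tnfaip3, 0.866 for Egr2, Cd3e, Cd4, Gata3, Klf2 and Tbx21, 0.895 for Actb, 0.897 for Myc, 0.902 for Irf4, 0.909 for Nfkbia, 0.915 for Nr4a1 and 0.969 for Ifng.

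By list, cytokine and chemokine genes were longer at 2 h than at 30 min (20 genes, 0 passing alone, median 0.19, mean 0.99, adjusted p = 0.0144; adjusted p = 0.529 with an estimated correlation). Immediate early genes were shorter (32 genes, median -0.18, and 0.14 with no centring, which turns the direction; adjusted p = 0.00890; adjusted p = 0.232 with an estimated correlation). Interferon response genes were shorter (24 genes, median -0.36, and -0.05 with no centring; adjusted p = 4.98e-06; adjusted p = 0.232 with an estimated correlation), with Igtp and Irf1 at -1.07 and -1.15 (adjusted p = 0.689 and 0.564). Cell cycle genes (25 genes, median -0.25, and 0.07 with no centring, which turns the direction; adjusted p = 0.00710; adjusted p = 0.232 with an estimated correlation) and histone genes (37 genes, median -0.30, and 0.02 with no centring, which turns the direction; adjusted p = 9.10e-09; adjusted p = 0.529 with an estimated correlation) were shorter. The other 13 tested lists did not pass.

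These list calls moved with single libraries. Without 30 min replicate 1 the adjusted p was 0.0606 for immediate early genes and 0.0638 for histone genes, and ribosome biogenesis passed (0.00884). Without 30 min replicate 2 it was 0.0974 for immediate early genes. Without 2 h replicate 1 it was 0.481 for cytokine and chemokine genes. Without 2 h replicate 2 it was 0.0522 for immediate early genes and 0.0596 for cell cycle genes, and glycolysis (0.00297) and ribosome biogenesis (0.00671) passed. By position cytokine and chemokine genes did not pass (0.0939) and ribosome biogenesis did (0.00183). Cytokine and chemokine genes did not pass with a pseudocount of 10 bp (0.0895), immediate early genes with a pseudocount of 1000 bp (0.111), quantile normalisation (0.292) or lists of equal length (0.0596), or cell cycle genes with no centring (0.0542), and none of these lists passed by the number of summits. For single genes, limma called 4 longer and 0 shorter without 30 min replicate 1, and 181 and 25 without 30 min replicate 2. In bp before centring, groups did not overlap for 1753 genes (17.7%, where exchangeable libraries give 33.3%). The shift of 30 min replicate 2 (0.341) lay between those of the 2 h libraries (0.147 and 0.382), which affects the share.

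Between 30 min and 2 h, 100 regions gained and 5 lost a peak, as did 74 and 10 genes (52 and 3 by position). With lists of equal length these were 108 and 44 regions, and 99 and 39 genes. The replicate split differed at 521 regions and 477 genes, and the crossed split at 34 and 39. Without 30 min replicate 1, 30 min replicate 2, 2 h replicate 1 and 2 h replicate 2 in turn, regions gained and lost were 101 and 428, 1438 and 10, 349 and 6, and 230 and 36. The genes were 108 and 226, 1313 and 157, 230 and 29, and 179 and 42.

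Both stimulated times were compared with the same NR libraries. Of the genes called, 20 were longer at both times and 1 shorter, where independent lists would share 0.0859 and 0.000606. A simulation gave 0 and 0 (50 draws). It drew all 6 libraries, NR included, as independent normal noise around the NR mean of each gene. With no change put in, few genes could pass, so its shared count of 0 says little. The log2 changes correlated across genes at 0.687 (simulated mean 0.498, highest 0.522), and genes are not independent replicates. The covariance was 0.455 against a simulated 0.208, a difference of 0.247. The simulated times shared their drawn controls but lacked the correlated deviations of same-numbered libraries. These were 0.44 for 30 min against NR, 0.27 for 2 h against NR and 0.41 for 2 h against 30 min. The simulation is thus no full baseline, and the controls were too few to split, so the source of the excess stays open.

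Markers of other blood cells were mostly without a promoter peak. Of 14 B cell markers 2 had one in any library (Cd74 and Ebf1), of 18 myeloid markers 1 (Cd68), of 15 erythroid and platelet markers 1 (Klf1), and of 12 CD8 and NK markers 4 (Cd8b1, Klrd1, Klrk1 and Nkg7). Cd68 had 848 ± 313 bp in NR cells, 5255.5 ± 4867 bp at 30 min and 5436 ± 4047 bp at 2 h, which did not pass (adjusted p = 0.521 and 0.337). The CD8 and NK list did not pass at 30 min (4 genes, median -0.15, mean 0.13, adjusted p = 0.956) or at 2 h (median 0.02, adjusted p = 0.634).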

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

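The tests of explanations and the counts of sites away from promoters in this part were chosen after the results they bear on were seen, and the list tests were set beforehand.

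Some lists drew attention because their changes at the 2 stimulated times differed when 2 h was tested against 30 min with camera and a preset correlation. Cytokine and chemokine genes were longer at 2 h (median 0.19, adjusted p = 0.0144), a call that ended by position (adjusted p = 0.0939). Interferon response genes were shorter (median -0.36, and -0.05 with no centring, adjusted p = 4.98e-06). Immediate early genes (-0.18, adjusted p = 0.00890), cell cycle genes (-0.25, adjusted p = 0.00710) and histone genes (-0.30, adjusted p = 9.10e-09) were shorter, and with no centring their medians turned to 0.14, 0.07 and 0.02. No list passed with an estimated correlation (adjusted p = 0.232 for immediate early, cell cycle and interferon response genes and 0.529 for cytokine and histone genes). Single libraries ended calls: adjusted p was 0.0606 for immediate early and 0.0638 for histone genes without 30 min replicate 1, 0.0974 for immediate early genes without 30 min replicate 2, 0.481 for cytokine genes without 2 h replicate 1, and 0.0522 for immediate early and 0.0596 for cell cycle genes without 2 h replicate 2.

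Peaks away from promoters entered the comparisons of genes only through the number of summits. Their summits, joined within 500 bp, form 22405 sites. At 30 min 491 sites had a summit in both libraries and in neither NR library, and 147 the reverse, while the crossed split differed at 287 sites and the replicate split at 1792. At 2 h 1801 sites were gained and 284 lost, against 157 in the crossed split and 932 in the replicate split. Of the gained sites 248 and 998 lay in a gene. The direction turned with single replicates: within replicate 1 gains and losses were 1733 and 6313 at 30 min and 4533 and 6027 at 2 h, and within replicate 2 they were 6647 and 853, and 5454 and 1268.

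Genes listed as having lost their promoter peak numbered 38 at 30 min and 69 at 2 h. Of the 28 and 45 with a value by position, 71.4% and 82.2% kept a called peak in all 4 libraries, so assignment of the same DNA to an overlapping gene is a candidate explanation for most of them. By position 1 gene lost its peak at 30 min (crossed split 7) and 10 at 2 h (crossed split 6), so polymerase leaving promoters gained no weight at 30 min and stays open at 2 h. Without NR replicate 1, NR replicate 2 and the stimulated replicates 1 and 2 in turn, the lost genes numbered 109, 121, 118 and 663 at 30 min and 188, 175, 120 and 164 at 2 h. Genes listed as gained numbered 39 at 30 min and 268 at 2 h. By position 5 and 22 of these had a peak in all 4 libraries, and 13 and 65 had no value. Assignment of the same DNA to another gene is thus a candidate explanation for some gains as well.

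More promoter regions were gained than lost after restimulation. Within replicate 2 NR had the most inferred reads, and all its libraries were scaled to about 22.7 M. Gains there were still 9.19 times the losses at 30 min and 4.20 times at 2 h. That argues against lower NR depth within replicate 2 only, with 1 library per group. Without the shallow NR replicate 1, regions lost rose from 2 to 85 at 30 min and from 19 to 170 at 2 h. Depth therefore stays open for the counts over both replicates. Within replicate 1 the ratio was 0.532 at 30 min, so differences in enrichment between single immunoprecipitations may account for the 30 min pattern, which also turned without NR replicate 1 (48 gained and 85 lost) and without 30 min replicate 2 (51 and 664). At 2 h the replicate 1 ratio was 9.19, on the same side as replicate 2, but called length was also greater at 2 h in both replicates (1.63 and 1.52 times), so enrichment stays open. With lists of equal length the ratios were 1.84 (crossed split 4.89) and 1.98 (crossed split 1.69), which leaves list length open, and recruitment of polymerase by restimulation stays open as well.

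Housekeeping, ribosomal protein and pan T cell lists were longer at both times, and hold genes that T cells also use at rest. Random lists matched on called length argue against a dependence on length for the median of ribosomal protein genes, at percentile 100 at both times. Only medians were compared, and the mean log2 change of that list was 0.03 at 30 min and -0.13 at 2 h. For housekeeping genes, at 93.47 and 89.35, such a dependence is a candidate explanation, and for pan T cell genes, at 97.42 and 99.92, it stays open. The same test put other lists called longer inside the middle 95% of random lists: glycolysis (66.05), feedback regulators (90.09), the Th1 programme (91.36) and activation transcription factors (96.62) at 30 min, and the Th1 programme (85.49) and other T helper lineages (96.86) at 2 h. Quiescence genes, which did not pass camera, lay at 0.01 at 30 min. With an estimated correlation, the smallest adjusted p of the housekeeping, ribosomal protein and pan T cell lists was 0.0787. This does not show genes of a list moving together between libraries. For ribosomal protein genes the estimate was 0.00885, under the preset 0.01. For housekeeping and pan T cell genes, at 0.0434 and 0.131, such movement stays open. Housekeeping genes did not pass without NR replicate 2 (adjusted p = 0.0785 at 30 min and 0.400 at 2 h) or at 2 h without 2 h replicate 1 (0.0739) or by position (0.238), nor pan T cell genes at 30 min without 30 min replicate 2 (0.133).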

How the results depend on the processing

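Assignment by position and the background of all protein-coding genes were chosen after seeing the data, and all other alternative tests were set beforehand. With 2 libraries per group and depths from 4.58 M to 39.4 M reads, gene counts depended on most settings, and unless a cause is named it was not tested. Among genes named and list results, 665 gene and 549 list values kept their side of the threshold, with library removals left aside. Values that passed at neither setting count as kept whatever their direction. Of the rest, 70 and 78 no longer passed and 13 and 19 newly passed. Direction turned for 12 and 9, counted only where the main or the alternative setting passed. Leaving a group with 1 library assumes that it varies like the other groups.

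For genes called longer and shorter by limma, a pseudocount of 1000 bp gave 7 shorter at 30 min, 93 and 19 at 2 h, and 5 and 3 for 2 h against 30 min. No centring gave 1 shorter at 2 h, with splits of 19 and 1 at 30 min and 35 and 1 at 2 h. Quantile normalisation gave 86 and 24 at 2 h and 1 shorter for 2 h against 30 min. The stricter peak threshold gave 2 shorter at 2 h. Lists of equal length gave 71 and 15 at 2 h and 4 shorter for 2 h against 30 min. The number of summits, counted in gene spans with 1000 bp on each side, gave 67 and 40, 137 and 41, and 91 and 31, and shared 1 longer and 0 shorter genes with the 30 min calls; a wide peak may hold few summits, by construction. Assignment by position gave 14 and 0, and 24 and 0, and is capped at a gene's span with its flanks. Only the 4 libraries of a contrast gave 13 and 3, and 148 and 25. Without 1 library the calls ran from 4 to 53 longer and 0 to 175 shorter at 30 min, 3 to 145 and 0 to 41 at 2 h, and 0 to 181 and 0 to 25 for 2 h against 30 min.

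Replicate numbers are shared by only 2 pairs per contrast and do not show that libraries were paired. The deviations of same-numbered libraries correlated at 0.44, 0.27 and 0.41 in the 3 contrasts. With replicate number as a block limma called 18 longer and 1 shorter, 28 and 5, and 0 and 0, of which 16 and 1, and 24 and 5 were shared, and the list counts stayed at 13 and 1, 12 and 2, and 1 and 4. In fits of the 4 libraries, the groups gave 16 genes at 30 min where replicate 1 against 2 gave 835, which points to a structure of the samples, and 173 at 2 h where the highest other split gave 0. For 2 h against 30 min they gave 0 and 13. With 3 splits no share under 0.05 is possible.

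Of genes with a promoter peak, lists of equal length gave 97 gained and 66 lost at 30 min, 152 lost at 2 h and 39 lost for 2 h against 30 min. Assignment by position gave 25 and 1, 10 lost and 3 lost. Of regions, the stricter threshold gave 1 lost at 30 min, and equal length gave 103 and 56 at 30 min, 123 lost at 2 h and 44 lost for 2 h against 30 min. The overlap alternative joined peaks that overlap by 50% of the shorter one. Without 1 library, genes gained and lost ran from 48 to 474 and 109 to 663 at 30 min, 286 to 1103 and 120 to 188 at 2 h, and 108 to 1313 and 29 to 226 for 2 h against 30 min. Regions ran from 48 to 762 and 2 to 664, 344 to 1216 and 22 to 170, and 101 to 1438 and 6 to 428.

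Of the fixed lists called longer and shorter, an estimated correlation left 1 and 0 at 30 min, 0 and 0 at 2 h, and 0 and 0 for 2 h against 30 min. Quantile normalisation gave 8 and 2 at 30 min and 5 longer for 2 h against 30 min. The number of summits gave 1 and 0, 1 and 0, and 0 and 0. Assignment by position gave 0 shorter at 30 min, 9 longer and 1 shorter at 2 h, and 1 longer for 2 h against 30 min, where ribosome biogenesis replaced cytokine genes, with histone genes absent, and no centring 1 shorter at 2 h. For 2 h against 30 min, 5 were longer with a pseudocount of 1000 bp, 0 with 10 bp, 2 with no centring and 2 with the stricter threshold. Without 1 library, lists ran from 6 to 13 longer and 0 to 1 shorter at 30 min, 9 to 13 and 2 to 2 at 2 h, and 0 to 3 and 2 to 4 for 2 h against 30 min. Among genes gained at 30 min, 0 lists were enriched with equal length and 2 by position. With a background of all protein-coding genes with no NR peak, under either assignment, 2 were enriched at 30 min and 3 at 2 h.

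By summits the direction turned for activation transcription factors, the Th1 programme and housekeeping genes (adjusted p = 0.720 for each) and ribosomal protein genes (0.768) at 30 min, and at 2 h for immediate early (0.712), Th1 programme and cell cycle (0.966 for both), housekeeping (0.357) and ribosomal protein genes (0.303). Histone genes at 30 min turned without 30 min replicate 2 (0.925), and without 1 library their adjusted p ran from 7.65e-11 to 0.925. Log2 changes by summits were -0.37 and -0.98 for Cd40lg at 30 min and 2 h, -1.53 for Hcst at 30 min, -0.61 for Nfkbia at both times, -0.74 for Lilrb4a, -0.37 for Fes and 0.98 for Rps3a1 and Obsl1 at 2 h. By position Shisa5 gave 0.051 at 30 min and Rps3a1 and Obsl1 1.43 and 0.74 at 2 h. Promoter peaks only and distal peaks included were not run, since the annotated tables hold only promoter peaks.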

Other observations

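All tests in this part were chosen after the results were seen.

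Some cytokine loci carried summits away from promoters that appeared with restimulation. Around Ifng (chromosome 10, 118441046 to 118445894) 24 sites lay within 50 kb, of which 3 at 30 min and 6 at 2 h were in both stimulated libraries and in neither NR library, and 1 was lost at 2 h. Around Il10 (chromosome 1, 131019845 to 131024970) 3 and 8 of 19 sites were gained in the same way. Both loci were chosen after seeing the counts. Between 30 min and 2 h, 14 of 56 sites near immediate early genes were gained (25.0%, against 5.70% of all sites with no 30 min summit; one-sided Fisher's exact test, adjusted p = 3.88e-05). Near cytokine and chemokine genes 15 of 67 were (22.4%, adjusted p = 3.88e-05) and near feedback and mRNA decay regulators 9 of 50 (18.0%, adjusted p = 0.0121). Sites cluster at single loci but were tested as if independent, so the p-values of these site tests may be too small. No locus of an immediate early gene or feedback regulator was left out. At 100 kb activation transcription factors (adjusted p = 0.00436), other T helper lineages and cell cycle genes (0.0171 for both) and pan T cell genes (0.0499) passed as well, so the gain was not particular to the first 3 lists. At 2 h against NR neither immediate early genes (29 of 146 sites, 19.9% against 17.3%, adjusted p = 0.969) nor feedback regulators (adjusted p = 0.653) passed. Over all sites 528 were gained and 143 lost between these times, while the crossed split differed at 378 sites and the replicate split at 2586. The direction turned within replicate 2 (2614 gained and 4222 lost, against 4208 and 1122 within replicate 1). At 30 min against NR the interferon response list led, with an adjusted p of 0.0303 at 50 kb, 0.0401 at 20 kb and 0.0756 at 100 kb. At 2 h against NR this list did not pass, with 10 of 94 sites gained (10.6%, against 17.3% of all such sites; adjusted p = 0.996 at 50 kb).

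Recruitment of polymerase to sites around cytokine genes may explain gains there at 2 h, which remains a hypothesis. Of sites with no NR summit near listed cytokine genes, all of which have a summit in some stimulated library, 32 of 112 were gained at 2 h (28.6%, against 17.3% of all such sites; one-sided Fisher's exact test, adjusted p = 0.0420 at 50 kb). The adjusted p was 0.237 at 20 kb, 0.0482 at 100 kb, and at 50 kb 0.570 without the Il10 locus and 0.220 without the Ifng locus. The share was 24 of 94 (25.5%) without Il10 and 26 of 96 (27.1%) without Ifng, so the call ended without either locus while the share stayed above that of all sites, and the question stays open.

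Polymerase still moving along long genes at 30 min could leave more of them to be covered at 2 h. Of 39 genes of the activation lists at least 20 kb long, 15 were longer by position in both 2 h libraries than in both 30 min libraries (38.5%, chance 16.7%), among them Stat5a, Cd200 and Cd274, against 969 of 5742 other genes of that size (16.9%; one-sided Fisher's exact p = 0.00114). It was 0.00554 at 10 kb or more and 0.228 at 50 kb or more. Random long genes matched on called length gave a median of 5 and a highest value of 14, which puts the observed 15 at percentile 100. Among genes of at most 5 kb 6 of 30 were longer (one-sided Fisher's exact p = 0.343) and of those between 5 and 20 kb 8 of 47 (17.0%, against 17.0% of other genes; p = 0.556), and the difference between long and short genes was not tested. The value by position holds only peaks of the promoter class, so separate peaks further inside a gene are not counted. The test therefore cannot follow polymerase along a long gene beyond peaks that reach out from promoters. A stronger response at 2 h of any kind would give the same picture, and the test was not run without single libraries, so the hypothesis stays open.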
